A study of Eohaustorius estuarius with 16 samples.

How the data were processed

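Total RNA from whole bodies of the estuarine amphipod Eohaustorius estuarius was measured on 1-colour (Cy3) Agilent arrays after 10 days in sediment spiked with the pyrethroid insecticide cyfluthrin at a nominal 1.6 µg/kg or in sediment spiked with solvent alone. The series is the part of an interlaboratory study in which a single laboratory made the RNA extracts and 6 laboratories labelled and hybridised them; the arrays analysed here are those of laboratory B. There were 8 control and 8 cyfluthrin arrays, assigned to their groups by the titles of the samples. The design text counts 8 control and 8 exposed amphipods, and the labels do not say whether an extract held a single animal or which animals shared a container, so p-values measure the spread between these samples only.

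The deposited scanner files give each spot's processed signal, an intensity that was background-subtracted and detrended by Agilent Feature Extraction and not normalized between arrays, per the file headers. The version was 10.7.1.1 per the file headers and 9.1 per the submitters' processing notes. The authors' deposited value table is in log2 units. Its values matched quantile-normalized log2 processed signals in which each probe's median over the 16 arrays had been set to 0, with the direction kept; the column medians and the correlation of each column with values computed that way were checked, and the steps themselves are not given in the sources used here. No column of that table was left without a sample.

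Each array held 15208 spots of contigs, which are assembled transcript fragments known here by contig number alone, with no protein name, sequence or position. The 8507 contigs had a single probe each: 2249 had 1 spot per array, 6208 had 2, 7 had 10 and 43 had 11. The log2 processed signal was scaled by subtracting each array's 75th percentile over these spots. Control spots were left out, spots that the software marked as non-uniform or population outliers were set aside, and the spots of a contig were averaged. A contig was tested when at least 50% of its spots were well above background on at least 8 of the 16 arrays whatever their group; 7574 contigs met this and 933 did not. Saturated spots were kept. The number of arrays, not the depth of a library, limits the precision.

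The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, Benjamini-Hochberg adjustment over the contigs tested, threshold 0.05), with no covariate. All log2 changes are cyfluthrin minus control. Because the arrays name contigs only, the contigs given by number were the 2 with the greatest rise and the 2 with the greatest fall among those past the threshold, a rule set before the data were examined. The 21 gene lists fixed at the same time need annotated names and could not be applied, so no gene set test was run. Agreement between arrays was the Pearson correlation of log2 values over the tested contigs, and comparisons of a single value used exact permutation over all 12870 choices of 8 of the 16 arrays.

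The file headers placed the arrays on 2 slides with 2 rows each. Each slide held 4 control and 4 cyfluthrin arrays, replicates 1 to 4 on slide 1 and 5 to 8 on slide 2. On each slide a group filled a row, and the rows were swapped between the slides. Slide and row were each entered as a block, and the comparison was repeated within each slide. Alternatives set beforehand were quantile and median normalization, background correction by normexp with an offset of 50, the authors' values, other filters, outlier spots kept, blocks for slide, row and replicate number, other variance models, array weights, other thresholds, and each array left out in turn. Normexp was run on the median signal, since the files hold no mean signal column. A further 5 settings were added after seeing the data: slide and row together, the half-slide as a random block, an array's 10th percentile as a covariate, scaling to spike-in probes, and cyfluthrin replicates 1 and 4 left out together. Control replicate 3 and cyfluthrin replicate 1, the lowest control and the highest cyfluthrin array in spike-in level, were also left out of the spike-in comparison, likewise after seeing the data. Of 10 spike-in probes, 5 were used, those above background and unsaturated on all arrays that followed the others with a correlation over 0.8, a rule corrected after a first form of it had kept fewer.

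The fit was tested on simulated data with the real contigs' means and spread, 8 and 8 arrays, and 200 of 7570 contigs changed. It recovered 27.5% of contigs changed by 0.50 on the log2 scale, 77.5% of those changed by 1.00 and 92.5% of those changed by 2.00, with 4, 12 and 11 false calls, and made 0 calls where no contig was changed. The simulated noise was independent between contigs and had the same SD in both groups. Real contigs varied together and most had a higher SD with cyfluthrin, so the false calls in the real data could differ.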

Results

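The arrays asked which transcripts of a sediment-dwelling amphipod differ in amount after 10 days in sediment spiked with cyfluthrin, a pyrethroid, from a class of insecticides that acts on the voltage-gated sodium channels of nerve cells. They also belong to a study of how comparable array data are between laboratories, of which laboratory B alone is analysed here. The groups held 8 control and 8 cyfluthrin arrays. The 75th percentile of the processed signal was 614 ± 88.4 in control and 636 ± 111 in cyfluthrin (SD, n = 8 each), and 86.9% ± 3.47 and 87.6% ± 5.0 of the spots were well above background. Neither measure differed between groups beyond the spread between arrays (exact permutation p = 0.668 and 0.751, 2-sided; adjusted p = 0.892 for both among 5 measures of the arrays).

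Between the cyfluthrin and the solvent control samples 561 of 7574 tested contigs differed, 7.41%, with 284 higher and 277 lower with cyfluthrin (limma, adjusted p under 0.05). At least 4-fold changes were found for 36 contigs that rose and 6 that fell, and at least 8-fold changes for 24 that rose and 0 that fell; after normexp background correction, 6 contigs rose at least 8-fold. The count of at least 4-fold falls was less stable than that of rises: leaving out each array in turn gave 5 to 10 falls and 35 to 36 rises, with 10 falls without cyfluthrin replicate 8, and array weights and spike-in scaling gave 11 falls each, with 35 and 31 rises. Most changes were smaller: the median log2 change was 0.58 among the contigs that rose and -0.59 among those that fell, and the quartiles of its size were 0.45 and 0.86. Without adjustment, 1652 contigs had p under 0.05, against 379 expected by chance. The median log2 change of all tested contigs was 0.01. The counts depended on the scaling and on the background correction. With each array scaled to its median, 163 contigs rose and 186 fell. After normexp background correction, which kept the 75th percentile scaling, 88 rose and 103 fell, with a median change of all contigs of 0.27. With scaling to spike-in probes, tried after seeing the data, the median of all contigs lay at -0.24, and 46 rose and 137 fell; the spike-in level relative to the 75th percentile, on which this shift rests, was 0.25 log2 units higher with cyfluthrin (exact permutation p = 0.2, 2-sided; adjusted p = 0.5 among 5 measures of the arrays), 0.14 without control replicate 3, 0.15 without cyfluthrin replicate 1 and 0.04 without both (exact permutation p = 0.75). Without both, the median of all contigs under spike-in scaling was 0.03. These were the control array with the lowest and the cyfluthrin array with the highest spike-in level. Leaving them out therefore had to lessen the difference in spike-in level.

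The greatest rise was that of contig_2303, 14.7-fold, from a log2 signal of -1.25 ± 0.92 relative to the array's 75th percentile in control to 2.63 ± 0.52 with cyfluthrin (SD, n = 8 each; log2 change 3.88, SE 0.35, limma adjusted p = 2.8e-06). The transcript of contig_4609 rose 13.3-fold, from -3.61 ± 0.72 to 0.12 ± 0.52 (log2 change 3.73, SE 0.30, limma adjusted p = 9.2e-07, n = 8 each); after normexp background correction its log2 change was 2.64. The greatest fall was that of contig_2561, by a factor of 6.14, from 2.78 ± 0.37 to 0.16 ± 0.29 (log2 change -2.62, SE 0.16, limma adjusted p = 6.1e-08, n = 8 each). The next was contig_3407, measured by 1 spot per array, which fell from 1.48 ± 0.39 to -1.12 ± 1.78 (log2 change -2.60, SE 0.60, limma adjusted p = 0.0136, n = 8 each). It was well above background on 7 of the 8 cyfluthrin arrays and not on that of replicate 4, where its log2 signal was -5.40, so the size of the fall and its place among the falls rest on that spot. Without that array the log2 change was -1.99 (SE 0.21, limma adjusted p = 2.6e-05). For each of these 4 contigs, all 8 cyfluthrin arrays lay beyond all 8 control arrays.

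**Figure D1:**
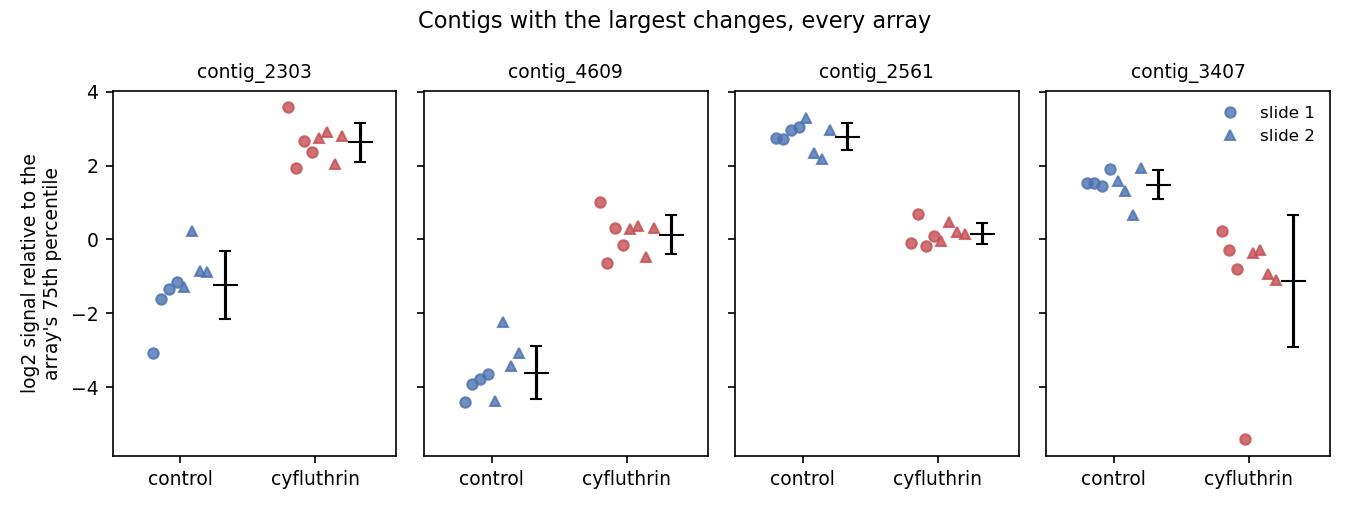
Log2 signal of the 4 named contigs relative to each array's 75th percentile (vertical axis) on the 8 control and 8 cyfluthrin arrays; circles are arrays of slide 1, triangles those of slide 2, and the black bar with whiskers is the group mean ± SD. The groups do not overlap in any of the 4 contigs, and cyfluthrin replicate 4 lies at -5.40 for contig_3407.

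Such complete separation of the groups was found for 85 of the contigs that rose and 56 of those that fell, and for 145 of all tested contigs, where chance gives a share of 0.0155%. The directions were not spread evenly over signal levels. Among the 2525 dimmest tested contigs 59 rose and 14 fell, among the middle 2524 123 rose and 57 fell, and among the 2525 brightest 102 rose and 206 fell. With quantile normalization the brightest were nearly balanced, with 160 that rose and 166 that fell, and among the dimmest 58 rose and 29 fell. With spike-in scaling, tried after seeing the data, 7 of the dimmest rose and 9 fell, and 22 of the brightest rose and 98 fell. That scaling shifted the median log2 change of all contigs to -0.24, which by itself removes rises. The brightest still leaned more to falls than the dimmest. After normexp background correction 8 of the dimmest rose and 0 fell, and 36 of the brightest rose and 97 fell. Of the contigs that rose, 2 were above background on no control array, and 0 of those that fell were above background on no cyfluthrin array. A spot was saturated on some array for 16 tested contigs, 1 of them among the changed ones.

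The comparison was repeated within each slide, with 4 control and 4 cyfluthrin arrays. Slide 1 alone gave 46 contigs that rose and 22 that fell (limma, adjusted p under 0.05). All 68 had the same direction on slide 2, and 64 of them had an unadjusted p under 0.05 there, against 11.99% of all tested contigs with that direction and p. Slide 2 alone gave 23 that rose and 14 that fell, and all 37 had the same direction and an unadjusted p under 0.05 on slide 1, against 8.70% of all tested contigs. There were 31 contigs called on both slides, where independent lists of these sizes would share 0.332. Across contigs, which are not independent replicates, the log2 changes of the 2 slides had r = 0.542 and Spearman's rho = 0.383. The log2 change of contig_2303 was 4.44 on slide 1 and 3.32 on slide 2, that of contig_4609 was 4.07 and 3.39, and that of contig_2561 was -2.74 and -2.50, each with limma adjusted p under 0.05 on both slides. For contig_3407 it was -3.16 on slide 1 (limma adjusted p = 0.407) and -2.04 on slide 2 (limma adjusted p = 0.0369). These named contigs were picked for large changes over both slides together, so their changes on each slide are no independent check. With slide as a block over all arrays, 258 contigs rose and 270 fell; with row as a block the counts were 262 and 262.

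**Figure D2:**
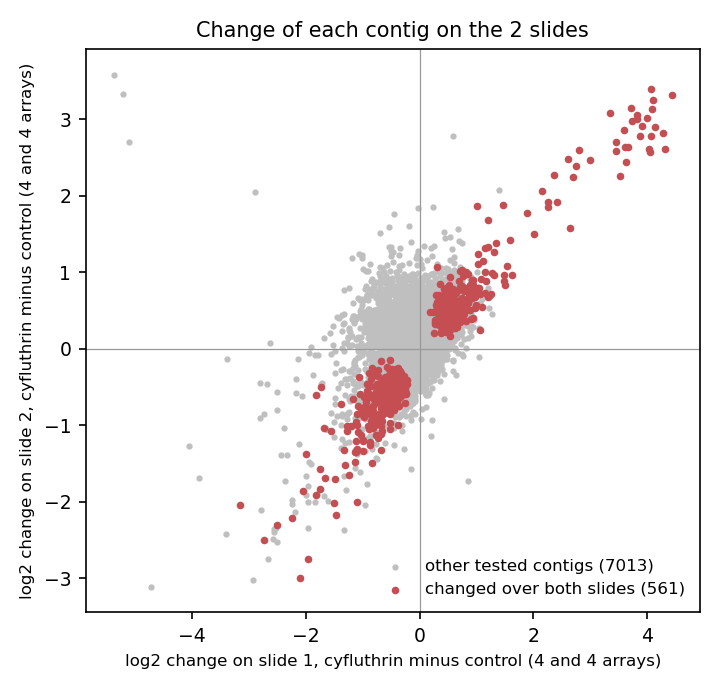
Log2 change of each tested contig, cyfluthrin minus control, on slide 1 (horizontal axis) and slide 2 (vertical axis), 4 arrays per group on each; red points are the 561 contigs changed over both slides together, grey points the other tested contigs. Over all points r was 0.542.

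The grouping by treatment accounted for 13.6% of the variance between the 16 arrays over the tested contigs, against 6.67% for an average split into groups of 8 (exact permutation p = 0.0188, 1-sided). With no filter on dim contigs the share was 11.6% (exact permutation p = 0.0503, 1-sided). The share of variance was not among the measures planned beforehand, and its p-values are unadjusted. Slide accounted for 3.76% and row for 4.64% (exact permutation p = 0.917 and 0.774, 1-sided). The first principal component held 26.2% of the variance and the second 22.5%, and their scores did not differ between groups beyond the spread between arrays (exact permutation p = 0.616 and 0.151, 2-sided; adjusted p = 0.616 and 0.302 among 4 components). The third held 13.3%, and group explained 66.9% of its scores (exact permutation p = 0.00031, 2-sided; adjusted p = 0.0012).

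**Figure D3:**
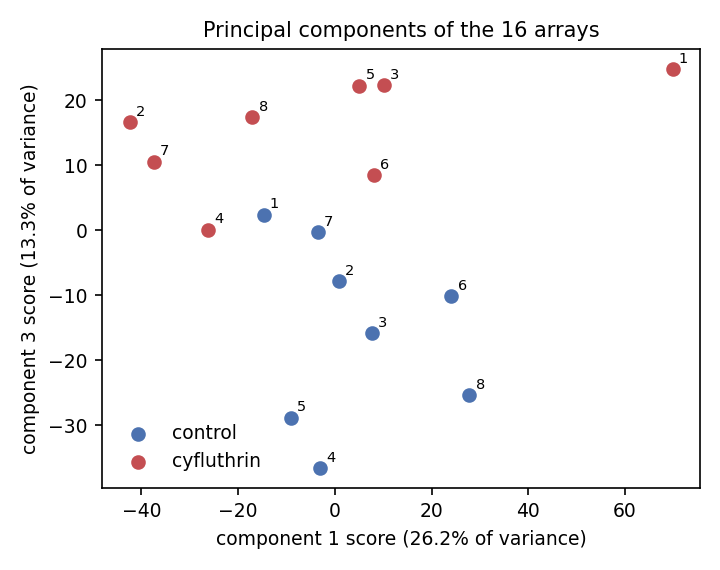
Scores of the 16 arrays on component 1 (horizontal axis, 26.2% of the variance) and component 3 (vertical axis, 13.3%); blue points are control arrays, red points cyfluthrin arrays, and the digits are replicate numbers. Along component 3 the lowest cyfluthrin score, 0.06 in replicate 4, lay below the highest control score, 2.40 in replicate 1, and cyfluthrin replicate 1 lies farthest out on component 1.

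Replicate arrays agreed more closely within groups than between them. The mean correlation of log2 values over the tested contigs was 0.955 among the 28 control pairs (0.920 to 0.983), 0.942 among the 28 cyfluthrin pairs (0.886 to 0.980) and 0.939 over the 64 pairs of a control and a cyfluthrin array; contigs are not independent replicates. The within-group mean exceeded the between-group mean by 0.0102 (exact permutation p = 0.0076, 1-sided). The mean correlation of an array with the others of its group was 0.955 ± 0.0089 in control and 0.942 ± 0.0121 with cyfluthrin (SD, n = 8 each; exact permutation p = 0.0208, 2-sided; adjusted p = 0.104 among 5 measures of the arrays), so this difference did not pass the correction; without cyfluthrin replicate 1 the difference was -0.0051 in place of -0.0133 (exact permutation p = 0.274, 2-sided). It was -0.0146 over the contigs well above background on all arrays (exact permutation p = 0.0054, 2-sided) and -0.0566 after normexp background correction (exact permutation p = 0.00016, 2-sided). The permutations for this difference shuffled each array's value as computed within its real group. Arrays of a group share pairs, so these values are not independent and the p-values of this difference are approximate only.

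The arrays of the cyfluthrin group varied more by a measure that was not planned beforehand and whose p-values are unadjusted. The SD between samples was higher with cyfluthrin than in control for 75.7% of the tested contigs (exact permutation p = 0.0099, 2-sided), with a median SD of 0.29 in control and 0.38 with cyfluthrin on the log2 scale. Without cyfluthrin replicate 1 and any 1 control the share was 63.1% to 70.8%, and the exact permutation p ran from 0.021 to 0.095. For the 5539 tested contigs with 2 spots per array, the median SD between the spots of an array was 0.10 and that between samples of a group 0.34, with a median ratio of 3.23.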

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

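The tests of row and of quantile normalization on the changed contigs, and those of leaving out control replicate 3 or cyfluthrin replicate 1, were chosen or given their bounds after the results they bear on were seen. An array was singled out when its gap to the nearest other array of its group, as a share of the group's range, passed Dixon's 95% value. This was applied to 18 groups of 8 arrays (5 measures of the arrays and the 4 named contigs, in each group) and singled out 2; chance gives about 1 in 20.

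For contig_3407, cyfluthrin replicate 4 had a log2 signal of -5.40 relative to its 75th percentile, not well above background, and the other 7 cyfluthrin arrays lay between -1.09 and 0.23. In control replicate 3 the spike-in probes, whose RNA is added in a fixed amount during labelling, lay 0.17 log2 units above the array's 75th percentile, and in the other 7 control arrays between 0.94 and 1.16. Without that array spike-in scaling gave 57 contigs that rose and 84 that fell, against 46 and 137 with it; without cyfluthrin replicate 1 it gave 52 and 99, and without both 81 and 95. The share of rises among these calls was 25.1% with all arrays, 40.4% without control replicate 3, 34.4% without cyfluthrin replicate 1 and 46.0% without both, and the median log2 change of all contigs was -0.24, -0.13, -0.08 and 0.03 in the same order. Cyfluthrin replicate 1 had the highest spike-in level of its group and control replicate 3 the lowest of its own. Leaving them out thus had to lessen the difference in spike-in level on which the shift rests.

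The 561 changed contigs were weighed against chance, row and the distribution of signals. Among 100 splits of the 16 arrays into groups of 8, 1 split, the real one, gave as many changed contigs, and the highest of the others gave 2. So many changes are thus unlikely by chance if the samples are independent. The splits cannot exclude chance differences between containers, which the labels do not give. A row effect would turn its sign between the slides, where the rows were swapped, but 68 of the 68 contigs called on slide 1 had the same direction on slide 2. With quantile normalization, which makes the distributions of all arrays equal, 464 of the 561 were still called in their direction, which argues against different distributions as the whole cause; with spike-in scaling 173 were still called, 373 kept an unadjusted p under 0.05 in their direction and 1 turned, and the median size of their log2 changes was 0.70 against 0.58. An effect of treatment, the comparison planned from the labels, remains the candidate explanation. Differences between containers or between animals that the labels do not give were not tested. Each row of a slide held 1 group only, so effects particular to a single row of a single slide were not separated from treatment.

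The wider spread between cyfluthrin samples was weighed against array-wide signal, spot noise and a single array. After quantile normalization the SD was still higher with cyfluthrin for 73.8% of contigs, and the 2 spots of a contig differed more with cyfluthrin for 50.6%. So neither the arrays' overall distributions of signal nor noise between the spots of an array accounts for a share of 75.7%. Each sample had a single array, so neither test tells differences in labelling or hybridisation from differences between samples. Without cyfluthrin replicate 1 the share fell to between 63.1% and 70.8%, depending on the control left out beside it, and the exact permutation p was under 0.05 for 3 of the 8 controls. The share thus stayed above the bound of 60% set at first, but that bound took no account of how far the share varies by chance. How much of the spread belongs to that array alone therefore stays open, and differences between animals in their response were not tested.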

How the results depend on the processing

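The half-slide, spike-in scaling, slide with row, and replicates 1 and 4 together were chosen after seeing the data. So were the settings for agreement without an array, spread and variance share. The measures of spread and of variance share were themselves not planned beforehand. Against 284 contigs that rose and 277 that fell, the rises moved by over 1.5 times with median normalization (163) and with the replicate number as a block (174). Both counts moved with normexp (88 and 103), adjusted p under 0.1 (476 and 463), a fold of at least 2 required (58 and 43), the half-slide as a random block (735 and 646) and spike-in scaling (46 and 137). For the named contigs the half-slide (correlation -0.118) lowered SEs and kept log2 changes. Thresholds aside, other causes were not tested. Spike-in scaling shifted the median log2 change of all contigs to -0.24 and normexp to 0.27. Under spike-in scaling 25.1% of the calls were rises, against 50.6%. Without control replicate 3 and cyfluthrin replicate 1, the lowest control and the highest cyfluthrin array in spike-in level, this share was 46.0% and the median 0.03. With spike-in scaling 1 of the 561 contigs turned direction, and with normexp 14. Rises of at least 8-fold numbered 6 with normexp, against 24. Leaving out each array in turn gave 214 to 397 rises and 200 to 394 falls, all within 1.5 times. Without cyfluthrin replicates 1 and 4 together the counts were 370 and 332, with slide and row as blocks 236 and 247. With the replicate block 191 fell. Same-numbered arrays shared slide and column. Correlations of same-numbered deviations from the group mean ran from -0.273 to 0.462, with a mean of 0.088. The mean of the other pairs, -0.013, is largely set by taking deviations from group means, so it is no independent comparison. Only 1 of 8 controls correlated best with its own number. No test was run, so whether the numbers pair the samples is not settled.

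The named contigs kept direction and limma adjusted p under 0.05 in all 33 settings run (32 for contig_3407, which the filter on all arrays left out), with log2 changes of 3.36 to 4.09 for contig_2303, 2.64 to 3.93 for contig_4609, -2.87 to -2.53 for contig_2561 and -2.85 to -1.91 for contig_3407. The lower agreement of cyfluthrin arrays with their own group, -0.0133, was -0.0051 without cyfluthrin replicate 1 (exact permutation p = 0.274) and -0.0566 with normexp (exact permutation p = 0.00016). These p-values are approximate only, since arrays of a group share pairs. The share of contigs with the higher SD in cyfluthrin kept its direction throughout; without cyfluthrin replicate 1 it ran from 63.1% to 70.8% over the controls left out beside it, and with control 1, 2, 6, 7 or 8 out it was 67.0%, 63.1%, 65.1%, 66.0% and 67.8% (exact permutation p = 0.066, 0.095, 0.088, 0.061 and 0.051), and without replicate 6 of both groups 72.3% (p = 0.055, exact permutation); over the numbers left out it ran from 67.0% to 79.7%. The variance with treatment was 11.6% with no filter (exact permutation p = 0.0503). The cause of these was not tested. Agreement from the authors' values and gene lists were not run. Background limited the test to 7574 contigs.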

Other observations

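The test of covariation among the induced contigs was chosen after the result was seen, as were the contigs and properties described after it.

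The 36 contigs that rose at least 4-fold had a mean log2 signal between -2.93 and -1.20 relative to the 75th percentile on the control arrays and between 0.10 and 1.65 on the cyfluthrin arrays. They also varied together where no cyfluthrin had been added: over the 8 control arrays their mean pairwise correlation was 0.509, above all 1000 random lists of contigs matched on control mean and SD, whose mean was 0.135 and highest value 0.379. Control replicate 6 had the highest mean of the induced contigs, -1.20, against -2.93 to -2.0 on the other control arrays; without it the correlation was 0.354, above 99.9% of lists matched on the other 7, whose highest was 0.356, and without any other control it was 0.496 to 0.5995. With quantile normalization the value over all 8 was 0.589 and the highest matched list 0.228. A candidate explanation, as a hypothesis, is a shared programme of expression that already varies between control samples; several contigs that come from the same transcript or cross-hybridise could give the same values, and without sequences this stays open.

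There were 57 tested contigs, 0.753%, whose log2 signal ranged over at least 8 units across the 16 arrays; for 40 the range was as wide within the control arrays alone. A contig of such spread can hardly pass the test: the median SE of its log2 change was 1.39, against 0.17 over all tested contigs, and 0 of the 57 were among the 561 changed (limma, adjusted p under 0.05; 3 had an unadjusted p under 0.05). All 57 had a lower mean with cyfluthrin, with log2 changes from -3.92 to -0.01 and limma adjusted p of 0.0797 or more. They varied together (mean pairwise correlation 0.462 over the 16 arrays), and 1.99% of all choices of 8 of the 16 arrays gave all of them the same sign. Their mean log2 signal was 0.15 ± 2.09 in control and -1.25 ± 2.12 with cyfluthrin (SD, n = 8 each; exact permutation p = 0.202, 2-sided), so whether they differ with treatment is not settled. The widest was contig_274, whose log2 signal ran from -7.30 to 5.58 (log2 change with cyfluthrin -0.19, limma adjusted p = 0.978). It was -7.30 and -5.82 in control replicates 4 and 5 and -4.92 and -6.31 in cyfluthrin replicates 4 and 7, -0.05 in cyfluthrin replicate 2, and between 2.45 and 5.58 on the other arrays. For contig_766 the log2 signal was between -7.04 and -5.73 in control replicates 6 and 7 and cyfluthrin replicates 1 and 3, and between -0.06 and 3.64 on the other 12. Of 12 contigs whose sorted values held a gap of at least 3 log2 units with 2 or more arrays on each side, 3 had their low values on the first set of 4 arrays and 3 on the second. On these sets contig_274 and contig_766 lay below the 10th percentile of the array, which ran from -5.25 to -3.50 over the 16 arrays. How far the wide ranges and gaps rest on signals near background was not examined.

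The changed contigs were sorted by probe number within each part of the array design. Each was paired with the next when their numbers lay within 5 of each other. Of these 112 pairs, 64.3% shared direction. The mean over 10000 random orders of the directions within each part was 51.3%, and 99.7% of the orders gave a lower share.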
